A study of Rattus norvegicus with 15 samples.

How the data were processed

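Polyadenylated RNA of isolated islets from 15 Lewis rats (10 Px and 5 Sham) was measured by sequencing. Per the labels' protocols, RNA was extracted with a miRNeasy kit and libraries were made with a directional kit given as Wafergreen Directional, and the rats are described as 4-5 weeks old, without saying at which point of the study. The average blood glucose of each rat is part of its sample title, whose further mark "Inc_YES" is not explained in the sources used here.

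The deposited count table holds raw read counts per gene for 28914 genes, with gene positions, strand and exon length in the featureCounts layout per the file headers. Per the submitters' processing notes the authors used FastQC, Subread, featureCounts and limma, without versions. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Gene symbols were used as the file gives them, including 25 symbols that have the form of dates. The deposited comparison table holds, per the file headers, log2 fold changes, average log2 expression, p-values and adjusted p-values per gene, and a fold-change column that equals 2 to the power of the log2 fold change (a ratio). Its header names no contrast, and its sign, checked against the counts, is Px relative to Sham. Its model was not stated per the file headers; a limma voom fit of Px against Sham on the counts gave a median absolute difference of 5.67e-05 from its log2 fold changes. It was used only for the comparison named in the results, and 20 of its symbols were absent from the count table. The deposited exon length column (in bases) was not used.

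Groups were Sham (n = 5), lower-glucose Px (n = 7) and higher-glucose Px (n = 3), with the boundary at a glucose of 300 set from the labels alone. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15) and libraries scaled by TMM. Tests were two-sided quasi-likelihood tests of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. All Px against Sham was a fit of 2 groups. The 3 other group comparisons came from 1 fit of 3 groups, and the slope on log2 glucose from the 7 lower-glucose libraries. Gene lists (28 lists, 525 genes, 500 in the count table) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, against the same test with an estimated correlation and fry, adjusted over the lists. With an estimated correlation no list passed in any of the 4 comparisons. Member counts are given over all genes and adjusted over the list alone where these differ. Comparisons of single measures are exact permutation tests over all splits (3003 for Px against Sham, 120 for higher- against lower-glucose Px), two-sided.

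The lists are islet hormones, beta cell transcription factors, beta cell glucose sensing and insulin secretion, beta cell disallowed genes, progenitor and dedifferentiation genes, markers of alpha, delta and PP, acinar, duct and endothelial cells, fibroblast, stellate cell and matrix genes, macrophage and myeloid markers, lymphocyte markers, antigen presentation and interferon response, unfolded protein response, antioxidant and redox genes, glycolysis, mitochondrial respiratory chain, cell cycle, senescence and cell cycle inhibitors, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, hypoxia response, immediate early genes, inflammatory signalling, mitochondrially encoded transcripts and cytosolic ribosomal proteins. Several genes sit on 2 lists, such as Hk1 and Ldha (disallowed and glycolysis). Disallowed genes are by definition expressed in other tissues.

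Named genes passed the threshold, had a mean of at least 5 CPM, a symbol that is not a locus identifier, and every library of the first group on the same side of the other group's mean. Of these the 10 largest rises and falls for Px against Sham, 8 for the other group comparisons and 5 for the slope could be named, with up to 2 rising and 2 falling members of each list by smallest p, and a fixed panel of which 17 genes were in the count table. The text leaves out some for length, and some are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

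Scores are means of log2 CPM over a list. Alternatives tried were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma voom with and without sample weights, a minimum absolute log2 fold change of 1, other groupings of the libraries, an acinar covariate and leaving out each library in turn, with further scalings, covariates and a thinning of the counts added after seeing the data. Library totals of 12.2 to 33.4 M set the depth, and shares carry 95% Wilson intervals that cover counting error only. The fits were tested on simulated counts drawn from the real genes' means and library sizes, with 50 genes changed at each of 4 fold sizes. All other genes had the same mean in every group, so bias from differing cell content was not tested. Among 28 simulated lists of randomly drawn genes, which varied independently of each other, the planted list was called (1 of 1) and 0 of the unchanged lists were. No library was left out of the main comparisons, and no pair of libraries within a group was a copy of another.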

Results

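Messenger RNA was sequenced from the isolated islets of Langerhans of 15 Lewis rats, 10 weeks after surgery. In 10 rats 90% of the pancreas had been removed (partial pancreatectomy, Px), which leaves a small remnant to control blood glucose, and 5 rats had a sham operation. Each label gives the rat's average blood glucose before tissue collection, without a unit. The Sham rats lay between 88 and 96, 7 Px rats between 104 and 211 (lower-glucose Px), and 3 Px rats between 416 and 464 (higher-glucose Px). Each library is taken as a separate rat, as far as the label numbering tells. Library totals ran from 12.2 to 18.4 M counts in Sham, from 19.1 to 31.6 M in lower-glucose Px and from 22.3 to 33.4 M in higher-glucose Px, over 28914 genes. Totals were higher in Px (26.72 ± 5.138 M, SD, n = 10) than in Sham (14.88 ± 2.925 M, SD, n = 5, exact two-sided permutation test, p = 0.000666).

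The libraries also differed in the share of counts from acinar cell markers, the digestive-enzyme genes of the exocrine pancreas. The share was 5.688% ± 5.977 (SD, n = 5) in Sham and 35.34% ± 10.2 (SD, n = 10) in Px (exact two-sided permutation test, p = 0.000333). The 8 islet hormone genes took 17.5% ± 5.028 of the counts in Sham and 6.321% ± 2.133 in Px (exact two-sided permutation test, p = 0.000333). Higher- and lower-glucose Px did not differ detectably in the acinar share (39% ± 5.174, n = 3, against 33.77% ± 11.72, n = 7, exact two-sided permutation test, p = 0.483). Single Sham libraries lay between replicate 23 (95% Wilson interval of the acinar share 1.141% to 1.153%) and replicate 25 (16.12% to 16.15%), and single Px libraries between lower-glucose replicates 8 (22.18% to 22.21%) and 16 (52.54% to 52.58%). These intervals cover counting error only. Below, expression is given as counts per M on TMM-scaled library sizes (CPM, mean ± SD over 5 Sham, 10 Px, 7 lower-glucose or 3 higher-glucose libraries), and changes as log2 fold changes ± standard error. Positions are those of the count table, whose genome build is not given in the sources used here.

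**Figure D1:**
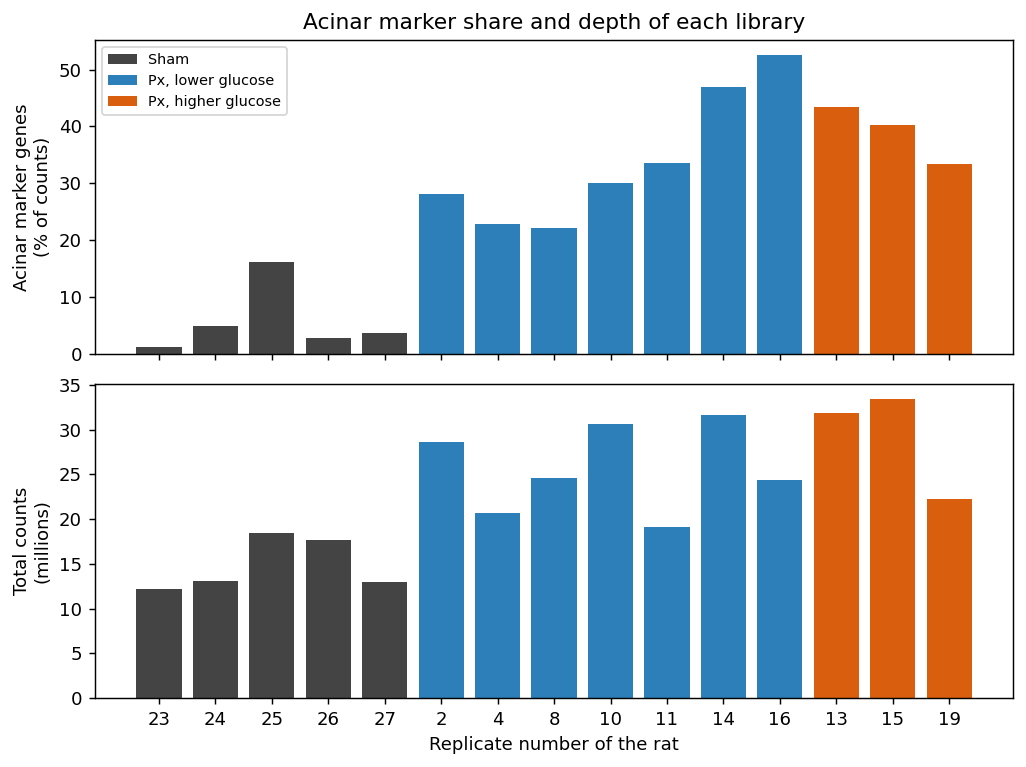
Acinar marker share of counts (upper panel, percent) and total counts (lower panel, M) of each of the 15 libraries, 1 bar per rat, by replicate number and coloured by group. The acinar share lies at or below 16.1% in the 5 Sham libraries and at or above 22.2% in the 10 Px libraries, which also hold more counts in total.

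The comparison of all Px with Sham islets asks how the islet transcriptome differed 10 weeks after most of the pancreas was removed. The genes that give the beta cell its identity were lower in Px. Nkx6-1 (chromosome 14, 9555264 to 9562189), a transcription factor that maintains beta cells, fell from 229 ± 25.8 to 75.5 ± 11.5 CPM (log2 fold change −1.60 ± 0.11, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 9.33e-09), and all 10 Px libraries lay below the lowest Sham library. Ucn3 (chromosome 17, 69960160 to 69966099), a peptide made by mature beta cells, fell from 266 ± 36.5 to 81.2 ± 18.6 CPM (−1.71 ± 0.15). Slc2a2, the glucose transporter GLUT2, fell from 1800 ± 165 to 797 ± 168 CPM (−1.18 ± 0.15), and Glp1r (chromosome 20, 9586075 to 9626228), the incretin receptor, from 227 ± 16.5 to 74.5 ± 16.3 CPM (−1.61 ± 0.13, all at edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 3.4e-06 or below). Genes that beta cells normally keep silent were higher: Ldha, lactate dehydrogenase, rose from 3.65 ± 0.866 to 39.7 ± 24.2 CPM (3.43 ± 0.37), and Hk1, a hexokinase with high glucose affinity, from 11.4 ± 2.26 to 51.8 ± 8.45 CPM (2.18 ± 0.15, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 8.28e-07 or below). Markers of macrophages, fibroblasts and acinar cells were higher in the same libraries.

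**Figure D2:**
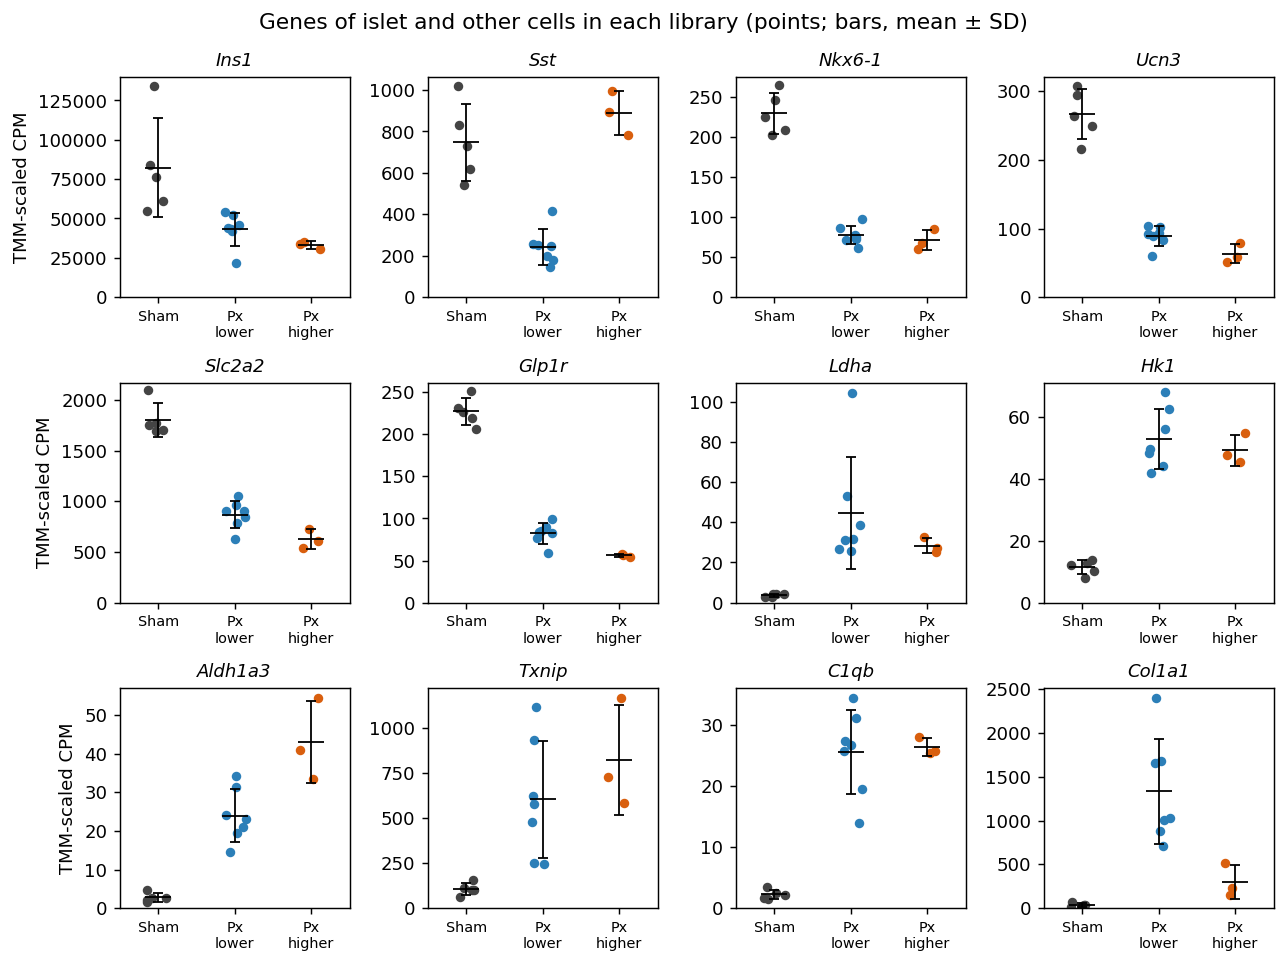
TMM-scaled CPM (vertical axes) of 12 genes in each library (points, 1 per rat) of Sham, lower-glucose Px and higher-glucose Px, with the mean ± SD of each group. Nkx6-1, Ucn3, Slc2a2 and Glp1r are lower and Ldha, Hk1, Aldh1a3 and C1qb higher in both Px groups than in Sham, and on this scale Sst is lowest in the lower-glucose group (241 ± 88 CPM).

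All 12 measured beta cell transcription factors were lower in Px (0 higher and 12 lower, median log2 fold change −0.97). Pdx1 fell by 0.93 ± 0.11, Mafa by 1.01 ± 0.27 and Isl1 by 1.10 ± 0.08 on the log2 scale, each ± its standard error (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00383 or below). Mafa did not pass with the acinar (−1.13, edgeR adjusted p = 0.258), macrophage (−0.38, 0.732) or fibroblast score (−0.25, 0.699) as a covariate or with endocrine scaling (−0.54, 0.0931), nor did Pdx1 with the macrophage score (−0.76, 0.0822). The group stood apart from other genes (camera with a preset correlation, Benjamini-Hochberg adjusted p = 2.57e-05, adjusted p = 0.231 with an estimated correlation). Of 31 genes of glucose sensing and insulin secretion, 27 were lower and 1, Adcy5, an adenylate cyclase (1.5 ± 0.19), was higher (median −0.88, camera adjusted p = 2.28e-08, and 0.231 with an estimated correlation). Ffar1, a fatty acid receptor of beta cells, fell by 1.31 ± 0.10. When libraries were scaled by 8 endocrine granule genes (Chga, Chgb, Scg2, Scg3, Scg5, Cpe, Pcsk2 and Pam) in place of TMM, 7 transcription factors and 18 secretion genes were still lower, and by library totals alone all 12 and 29. Of the 8 scaling genes 5 are themselves on the secretion list. Some of the strongest falls were in genes outside the lists, with every Px library below the Sham mean. Cplx2, a complexin that clamps vesicle fusion, fell from 231 ± 40.1 to 43 ± 10.1 CPM (−2.42 ± 0.15). Syt12, a synaptotagmin (−2.75 ± 0.21), Nell1, a secreted growth-factor-like protein (−2.64 ± 0.18), and Cabp7, a calcium-binding protein (−2.58 ± 0.27), fell with it (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 5.8e-07 or below). Cabp7 lost its call with the macrophage score (−1.06, edgeR adjusted p = 0.254).

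The islet hormones moved less uniformly. Ins1 (chromosome 1, 272799784 to 272800347) was 82300 ± 31300 CPM in Sham and 40300 ± 9920 CPM in Px (−1.03 ± 0.31, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00816). Ins2 (chromosome 1, 215856971 to 215858034) was 21400 ± 9150 CPM in Sham and 11200 ± 4000 CPM in Px (−0.94 ± 0.31, adjusted p = 0.014 by the same edgeR test). These near-identical copies can share reads, so their separate values are uncertain. Without Sham replicate 26 Ins2 no longer passed (−0.67, edgeR adjusted p = 0.073), and with the acinar score as a covariate its sign changed (0.16). Ins1 did not pass with the acinar score (−0.21, edgeR adjusted p = 0.818), the acinar share (−0.84, 0.222), the macrophage score (−1.59, 0.159) or endocrine scaling (−0.52, 0.143), nor did Ins2 with the last 3 of these (−0.59, 0.428, −1.82, 0.106, and −0.40, 0.344). Of the 8 hormones 2 were higher and 2 lower (median −0.67, camera adjusted p = 0.393), against 2 higher and 0 lower with endocrine scaling and 0 higher and 6 lower with library totals. Ppy (0.70 ± 0.26) and Pyy (0.86 ± 0.26), peptides of PP cells, were higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0284 or below). Leaving out Sham replicate 23, 24, 25 or 27 ended the call for Ppy (edgeR adjusted p = 0.0629, 0.0534, 0.0554 and 0.0896, at 0.66, 0.69, 0.68 and 0.55). Neither Ppy nor Pyy passed by library totals (0.03 and 0.17, edgeR adjusted p = 0.921 and 0.556) or with the acinar score (0.76 and 0.49, 0.387 and 0.582) or share (0.72 and 0.44, 0.261 and 0.486), nor Ppy with the macrophage score (1.19, 0.17). Iapp, the amyloid peptide co-secreted with insulin (−0.56 ± 0.24), Gcg, glucagon (0.10 ± 0.28), and Sst, somatostatin (−0.78 ± 0.42), did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0503, 0.77 and 0.118). Iapp passed without higher-glucose replicate 13 (−0.61, edgeR adjusted p = 0.0451), higher-glucose replicate 19 (−0.65, 0.0254) or Sham replicate 23 (−0.63, 0.0426), and Sst without higher-glucose replicate 15 (−0.99, 0.0397). Iapp (−1.25, edgeR adjusted p = 0.000111), Sst (−1.60, 0.000179) and Gcg (−0.59, 0.0416) were lower by library totals alone, and Sst was lower with the acinar share (−2.36, 0.0483) and higher with the fibroblast score (1.22, 0.0431) as a covariate.

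Of 23 beta cell disallowed genes, which most tissues express and beta cells repress, 22 were higher and 0 lower (median 2.44, camera adjusted p = 4.71e-10, and 0.219 with an estimated correlation). Beside Ldha and Hk1, Zfp36l1, an RNA-binding protein, rose by 2.44 ± 0.13. The list was higher in the same libraries in which immune and matrix markers rose, and with the macrophage score as a covariate 16 of its members were still higher. Among 10 progenitor and dedifferentiation genes, 6 higher and 1 lower passed (median 1.19, camera adjusted p = 0.032, and 0.305 with an estimated correlation). Aldh1a3, a retinal dehydrogenase seen in dedifferentiating beta cells, rose from 2.77 ± 1.14 to 29.6 ± 11.8 CPM (3.42 ± 0.33). Myc, a growth regulator, rose by 3.14 ± 0.26, and Tnfrsf11b, osteoprotegerin, fell by 1.39 ± 0.20 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 1.24e-05 or below). Txnip, a glucose-induced inhibitor of thioredoxin, rose from 105 ± 33.1 to 669 ± 320 CPM (2.67 ± 0.38, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.24e-05). With the acinar score Txnip (1.67, edgeR adjusted p = 0.154) and Tnfrsf11b (−0.90, 0.131, and −0.87, 0.0503, with the acinar share) lost their calls.

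Markers of other cell types were higher in Px too. Macrophage and myeloid markers were higher in all 17 measured genes (median 4.11, camera adjusted p = 3.76e-09, and 0.305 with an estimated correlation). Among them were C1qb, a complement subunit made by macrophages (3.51 ± 0.23), and Csf1r, the macrophage growth-factor receptor (3.90 ± 0.31). Mmp12, the macrophage elastase, rose from 0.946 ± 0.624 to 126 ± 130 CPM (7.08 ± 0.95), with Mmp9, a gelatinase (8.20 ± 1.66), and Fcgr2b, an antibody receptor (6.79 ± 0.92). All 18 fibroblast, stellate cell and matrix genes were higher (median 3.56, camera adjusted p = 3.74e-08, and 0.305 with an estimated correlation), such as Dcn, decorin (3.26 ± 0.24), and Tagln, a smooth-muscle actin-binding protein (3.67 ± 0.28). Acinar markers were higher in 25 of 26 genes (median 3.32, camera adjusted p = 3.74e-08, and 0.382 with an estimated correlation): Reg1a, a regeneration-associated lectin, rose from 133 ± 150 to 4330 ± 1170 CPM (5.03 ± 0.62), and Rbpjl, an acinar transcription factor, by 3.89 ± 0.48. Trypsin and amylase copies on this list can share reads and are uncertain. Duct markers were higher in 11 of 13 genes (median 2.88, camera adjusted p = 0.000591, and 0.305 with an estimated correlation), with Spp1, osteopontin, at 4.62 ± 0.53 and Tspan8, a tetraspanin, at 2.88 ± 0.31. Of 11 endothelial markers 8 higher and 1 lower passed (median 0.93, camera adjusted p = 0.0235, and 0.465 with an estimated correlation). Tie1, an endothelial receptor, rose by 1.49 ± 0.17, and Ece1, the endothelin-converting enzyme, fell by 0.53 ± 0.13, although with the macrophage score as a covariate it was 0.07. The calls for Mmp12 (3.36, edgeR adjusted p = 0.122), Mmp9 (4.01, 0.404), Fcgr2b (2.72, 0.101), Spp1 (2.35, 0.0952) and Tie1 (1.07, 0.0543) ended with the macrophage score. Those for Reg1a (2.14, edgeR adjusted p = 0.13), Rbpjl (1.35, 0.145) and Mmp9 (7.33, 0.124) ended with the acinar score, and Ece1 was −0.08 with endocrine scaling and −0.02 with the fibroblast score. Reg1a and Rbpjl are part of the acinar score and Fcgr2b of the macrophage score, so each was adjusted in part for itself. Their losses follow in part by construction and do not test the source of their RNA. In the fit without covariates each gene named with these lists had an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0017 or below.

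Immune genes were also higher. All 7 lymphocyte markers were higher (median 4.24, camera adjusted p = 0.00267, and 0.361 with an estimated correlation), including Cd4 (2.74 ± 0.29) and Il7r, a T-cell survival receptor (5.07 ± 0.63). Antigen presentation and interferon response genes were higher in 23 of 24 (median 2.0, camera adjusted p = 2.89e-07, and 0.305 with an estimated correlation). RT1-Da, a class II histocompatibility gene whose relatives can share its reads, rose by 3.88 ± 0.39. Inflammatory signalling genes gave 15 higher and 1 lower (median 3.73, camera adjusted p = 9.52e-05, and 0.305 with an estimated correlation), with Ccl2, which attracts monocytes, at 5.10 ± 0.57. Immediate early genes gave 12 higher and 1 lower (median 1.40, camera adjusted p = 0.00337, and 0.382 with an estimated correlation): Jun rose by 2.28 ± 0.13, and Nr4a1, an activity-induced nuclear receptor, fell by 1.11 ± 0.36, though it was 0.16 with the fibroblast score as a covariate. Antioxidant genes gave 11 higher and 1 lower (median 0.58, and −0.01 by library totals, camera adjusted p = 0.0114, and 0.305 with an estimated correlation), with Hmox1, heme oxygenase, at 4.10 ± 0.37 and Gpx1, a glutathione peroxidase, at 2.91 ± 0.28. Cell cycle genes gave 21 higher and 1 lower (median 1.22, camera adjusted p = 0.000748, and 0.465 with an estimated correlation). Mki67, a marker of dividing cells, rose by 1.76 ± 0.28 and Ccnd2, a cyclin of beta cell division, fell by 0.81 ± 0.14, but with the macrophage score as a covariate these were −0.13 and 0.13. Neither passed with the fibroblast score (0.37 and −0.23, edgeR adjusted p = 0.273 and 0.343), nor Il7r with the macrophage score (2.27, 0.0617), nor Nr4a1 with the acinar (−1.49, 0.245) or macrophage score (−0.31, 0.825) or the acinar share (−1.44, 0.152). In the fit without covariates the genes named for these lists each had an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.012 or below.

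Ribosomal protein genes were higher in 27 of 30 (median 0.96, camera adjusted p = 3.27e-07, and 0.305 with an estimated correlation), with Rpl23 at 2.18 ± 0.16. Nuclear genes of the respiratory chain gave 24 higher and 1 lower (median 0.47, camera adjusted p = 0.00193, and 0.504 with an estimated correlation), but 0 higher and 7 lower by library totals alone. With the acinar score as a covariate the camera adjusted p of this list was 0.85, that of antioxidant genes 0.157 and that of endothelial markers 0.0608, and fatty acid synthesis passed downward (0.0315). Ndufb3 (1.20 ± 0.15) and Ndufs1 (−0.37 ± 0.09), both subunits of complex I, moved apart, and Ndufs1 was 0.07 with endocrine scaling and 0.09 with the macrophage score as a covariate. The mitochondrially encoded transcripts were lower in 8 of 13 (median −0.44, camera adjusted p = 0.00267, and 0.431 with an estimated correlation), and in 1 with endocrine scaling. Mt-nd5, a complex I subunit, fell by 0.86 ± 0.12 (for all 4 genes, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00187 or below). Fatty acid synthesis gave 2 higher and 5 lower (median −0.26, camera adjusted p = 0.139, 3 higher and 1 lower with endocrine scaling), with Acly, which makes acetyl-CoA for lipids, at −1.06 ± 0.11. Cholesterol synthesis gave 2 higher and 8 lower, with a median of 0.03 and a downward test (camera adjusted p = 0.338, 0 higher and 15 lower by library totals, 9 higher and 0 lower with endocrine scaling). Its enzyme Hmgcs1 was at 0.51 ± 0.15, and at −0.13 by library totals (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00629 or below for Acly and Hmgcs1). The calls for Acly (−0.49, edgeR adjusted p = 0.15), Mt-nd5 (−0.64, 0.141) and Hmgcs1 (0.36, 0.477) ended with the macrophage score, for Hmgcs1 also with the acinar score (0.55, 0.257), and for Ndufb3 by library totals (0.56, 0.0626).

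The remaining lists did not stand apart in camera without a covariate, and most changed direction with the scaling. Alpha cell markers gave 6 higher and 0 lower (median 0.48, camera adjusted p = 0.167, 5 higher and 5 lower by library totals). Delta and PP cell markers gave 4 higher and 1 lower (0.12, camera adjusted p = 0.78, 1 higher and 4 lower by library totals). The unfolded protein response gave 6 higher and 4 lower (median 0.07, camera adjusted p = 0.961, 2 higher and 15 lower by library totals, 13 higher and 1 lower with endocrine scaling). With the acinar score as a covariate its camera test was downward at adjusted p = 0.0158. Glycolysis gave 7 higher and 6 lower (0.33, camera adjusted p = 0.743, 4 higher and 8 lower by library totals). Senescence genes and cell cycle inhibitors gave 5 higher and 2 lower (0.62, camera adjusted p = 0.507, 3 higher and 3 lower by library totals). Fatty acid oxidation gave 5 higher and 4 lower (median −0.00, mean 0.24 and a downward test, camera adjusted p = 0.942, 1 higher and 9 lower by library totals, 9 higher and 0 lower with endocrine scaling). The hypoxia response gave 5 higher and 6 lower, with a median of 0.05 and a downward test (camera adjusted p = 0.539, 2 higher and 7 lower by library totals). Adjusted over the list alone, the counts were 7 higher and 2 lower for progenitor genes, 5 and 0 for alpha, and 26 and 0 for acinar markers. They were 11 and 1 for duct, 9 and 1 for endothelial, 25 and 1 for respiratory chain, 22 and 1 for cell cycle and 5 and 4 for unfolded protein response genes, and for the other lists as over all genes.

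In total 9838 of 15199 tested genes passed, 5242 higher (53.3%) and 4596 lower, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The split depended on the scaling: library totals alone gave 2667 higher and 7950 lower (25.1% higher) and moved the median of all genes to −0.62. Endocrine scaling gave 7435 higher and 996 lower (88.2%) with a median of 0.46. The deposited comparison table, which follows the limma layout, lists 9671 of 15203 genes at an adjusted p under 0.05 (5055 higher and 4616 lower). Of these, 9503 also passed here, all with the same sign, and 153 passed only there and 322 only here among 15179 shared genes. On simulated counts, 36% of genes changed 1.5-fold, 76% of those changed 2-fold and 94% of those changed 4-fold were recovered in this comparison (15049 genes, 5.59% of 161 calls false). Few genes were changed in these simulated counts, so they do not test bias from the differing cell content of Px and Sham.

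The comparison of lower-glucose Px with Sham asks what had changed in rats whose glucose was nearer to that of Sham. Sst (chromosome 11, 80358211 to 80359444), somatostatin, the hormone of delta cells, fell from 747 ± 187 to 241 ± 88 CPM (−1.64 ± 0.22, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.65e-06). The beta cell genes were low in these rats: Nkx6-1 −1.57 ± 0.12, Pdx1 −0.98 ± 0.12, Ucn3 −1.59 ± 0.14, Slc2a2 −1.06 ± 0.13 and Glp1r −1.47 ± 0.10 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 4.28e-06 or below). With the macrophage score as a covariate these 5 values were −1.09, −0.94, −0.91, −0.55 and −0.77, and none passed (edgeR adjusted p from 0.077 to 0.49), nor did Sst (−1.65, 0.168, and −0.55, 0.484, with the fibroblast score). Ldha (3.59 ± 0.36), Hk1 (2.21 ± 0.15) and Aldh1a3 (3.11 ± 0.27) were higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 4.76e-07 or below). Beside them rose Vim, a mesenchymal filament (3.67 ± 0.28), Col6a2, a matrix collagen (3.79 ± 0.25), Spp1 (4.92 ± 0.42) and C1qb (3.49 ± 0.24, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 9.56e-08 or below for all 4). With the macrophage score Ldha (0.70, edgeR adjusted p = 0.394), Aldh1a3 (2.60, 0.0571) and Vim (1.91, 0.0679) lost their calls, and Hk1, Col6a2, Spp1 and C1qb kept theirs. Among the 28 genes named for this comparison in all, 18 lost their call with that score and 5 changed sign.

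Of the islet hormones 1 higher and 5 lower passed in lower-glucose Px (median −0.73, camera adjusted p = 0.176), against 2 higher and 1 lower with endocrine scaling. Ins1 (−0.93 ± 0.32), Ins2 (−0.74 ± 0.30) and Iapp (−0.71 ± 0.24) were lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0384 or below). Leaving out 1 library ended several of these calls by the same edgeR test: Ins1 without Sham replicate 26 (−0.68, adjusted p = 0.0753) and Iapp without Sham replicate 27 (−0.63, 0.0509). Ins2 lost its call without Sham replicates 23 (−0.74, edgeR adjusted p = 0.0536), 26 (−0.47, 0.166) or 27 (−0.73, 0.0652) and without lower-glucose replicates 4 (−0.71, 0.0669), 10 (−0.77, 0.0517), 11 (−0.61, 0.0648) or 14 (−0.72, 0.0638). Ins2 was 0.17 with the acinar score and Iapp 0.70 with the macrophage score as a covariate, and Ins1 did not pass with the acinar (−0.21, edgeR adjusted p = 0.8), macrophage (−1.19, 0.544) or fibroblast score (−1.21, 0.334) or with endocrine scaling (−0.32, 0.312). Ins2 did not pass with the macrophage (−0.92, edgeR adjusted p = 0.616) or fibroblast score (−1.01, 0.404) or endocrine scaling (−0.12, 0.731), nor Iapp with the acinar (−1.03, 0.11) or fibroblast score (−0.14, 0.904) or endocrine scaling (−0.17, 0.444). With the acinar share Ins1 was −0.84 (edgeR adjusted p = 0.205) and Ins2 −0.59 (0.377). Rbp4, a retinol carrier made by delta cells (−0.69 ± 0.15), was lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000593). Its call ended with the acinar (−0.60, edgeR adjusted p = 0.189), macrophage (−0.11, 0.925) and fibroblast scores (−0.45, 0.446) and with endocrine scaling (−0.12, 0.521). Delta and PP markers as a list gave 3 higher and 4 lower (median 0.02, with a downward camera test at adjusted p = 0.802).

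All 12 transcription factors (median −1.07, camera adjusted p = 1.96e-05, and 0.278 with an estimated correlation) and 27 of 31 secretion genes (−0.86, camera adjusted p = 1.15e-08, and 0.278 with an estimated correlation) were lower. In contrast, 22 of 23 disallowed genes were higher (2.41, camera adjusted p = 9.47e-10, and 0.278 with an estimated correlation). All 18 fibroblast and matrix genes (median 3.75, camera adjusted p = 1.62e-09, and 0.278 with an estimated correlation), all 17 macrophage markers (4.27, camera adjusted p = 2.78e-09, and 0.278 with an estimated correlation) and 25 of 26 acinar markers (3.12, camera adjusted p = 1.98e-07, and 0.376 with an estimated correlation) were higher. Cell cycle genes gave 23 higher and 2 lower (median 1.44, camera adjusted p = 1.44e-05, and 0.332 with an estimated correlation): Mki67 rose by 1.97 ± 0.22 and Mcm3, a replication licensing factor, by 2.62 ± 0.25 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 1.29e-06 or below). Neither passed with the macrophage (0.47 and 0.69, edgeR adjusted p = 0.612 and 0.318) or the fibroblast score (0.67 and 1.58, 0.287 and 0.0507). The mitochondrially encoded transcripts gave 0 higher and 9 lower (median −0.58, camera adjusted p = 0.000323, and 0.332 with an estimated correlation, 0 higher and 1 lower with endocrine scaling), with Mt-nd5 at −0.86 ± 0.13. Fatty acid synthesis gave 2 higher and 8 lower (median −0.41, camera adjusted p = 0.0438, and 0.425 with an estimated correlation), but 4 higher and 1 lower with endocrine scaling. Its desaturase Scd was at 2.47 ± 0.75, and at −1.22 with the macrophage score as a covariate. Hmgcs1 of the cholesterol pathway was at 0.36 ± 0.13, lost its call without Sham replicate 26 (0.32, edgeR adjusted p = 0.055), and was −0.10 by library totals, −0.60 with the macrophage score and −0.15 with the fibroblast score. Cplx2 (−2.40 ± 0.17) and Cabp7 (−2.87 ± 0.26) were lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0213 or below for these and for Mt-nd5, Scd and Hmgcs1). With the macrophage score Cplx2 (−1.58, edgeR adjusted p = 0.087), Cabp7 (−1.86, 0.22) and Mt-nd5 (−0.54, 0.478, and −0.67, 0.174, with the fibroblast score) lost their calls. So did Scd (2.02, edgeR adjusted p = 0.338) and Hmgcs1 (0.51, 0.172) with the acinar score, and Scd with the acinar share (2.21, 0.111) and the fibroblast score (3.08, 0.257). Adjusted over the list alone the counts were the same, apart from 0 higher and 11 lower for the mitochondrially encoded transcripts among the lists given for this comparison.

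Of 15661 tested genes 9949 passed in lower-glucose Px, 5257 higher (52.8%) and 4692 lower, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Library totals alone gave 3089 higher and 7134 lower (30.2% higher, median of all genes −0.48), and endocrine scaling 9032 higher and 869 lower (91.2%, median 0.58). On simulated counts, 58% of genes changed 2-fold and 90% of those changed 4-fold were recovered in this comparison (15138 genes).

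The comparison of higher-glucose Px with Sham covers the 3 rats with high blood glucose. Tdh, a threonine dehydrogenase, rose from 0.826 ± 0.546 to 78.3 ± 27.5 CPM (6.52 ± 0.49). Folr1, a folate receptor, rose by 5.93 ± 0.53 and Pfkfb3, an inducible activator of glycolysis, by 4.16 ± 0.29 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p of 3.6e-07 or below). Ins1 (−1.31 ± 0.43) and Ins2 (−1.56 ± 0.40) were lower. Ppy (1.17 ± 0.28), Pyy (1.44 ± 0.22) and Chgb, a secretory granule protein (1.0 ± 0.14), were higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0149 or below for all 5). The calls for Ins1 and Ins2 ended with the acinar score (−0.53 and −0.57, edgeR adjusted p = 0.563 and 0.542), the acinar share (−1.21 and −1.38, 0.139 and 0.0935) and the macrophage score (−1.50 and −1.69, 0.182 and 0.0995) as covariates. By library totals Ppy (0.17, edgeR adjusted p = 0.678), Pyy (0.46, 0.189) and Chgb (0.03, 0.918) did not pass, nor did Ppy with the acinar (1.46, 0.0751), macrophage (0.84, 0.309) or fibroblast score (0.90, 0.0634). Among beta cell genes Glp1r was at −2.02 ± 0.14, Ucn3 at −2.08 ± 0.19, Nkx6-1 at −1.70 ± 0.16, Slc2a2 at −1.53 ± 0.18 and Pdx1 at −0.84 ± 0.16 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.000271 or below). Pdx1 lost its call with the acinar (−0.77, edgeR adjusted p = 0.0809) or the macrophage score (−0.81, 0.0787). Slit1, an axon guidance factor, fell by 2.74 ± 0.21 on the log2 scale.

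Sst did not differ detectably from Sham (890 ± 106 against 747 ± 187 CPM, 0.25 ± 0.27, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.453), but was lower by library totals (−0.75, edgeR adjusted p = 0.0113). Under TMM Mafa did not pass either (−0.70 ± 0.37, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.115), but passed without Sham replicate 24 (−0.87, edgeR adjusted p = 0.0488) and by library totals (−1.74, 0.000205). 10 of 12 transcription factors (median −0.83, camera adjusted p = 0.000126, and 0.352 with an estimated correlation) and 27 of 31 secretion genes (−0.94, camera adjusted p = 2.24e-08, and 0.352 with an estimated correlation) were lower. All 23 disallowed genes were higher (median 2.14, camera adjusted p = 1.14e-09, and 0.344 with an estimated correlation), among them Ldha (2.94 ± 0.39) and Hk1 (2.11 ± 0.17), and so was Aldh1a3 (3.95 ± 0.30). Ldha lost its call with the macrophage score (0.94, edgeR adjusted p = 0.0696). Alpha cell markers gave 7 higher and 0 lower (median 0.82, camera adjusted p = 0.0309, and 0.352 with an estimated correlation), but 2 higher and 4 lower by library totals. Etv1, a transcription factor on the delta and PP list, was at 1.37 ± 0.18. Respiratory chain genes gave 26 higher and 0 lower (median 0.63, camera adjusted p = 6.04e-05, and 0.378 with an estimated correlation), but 0 higher and 9 lower by library totals and camera adjusted p = 0.116 with the acinar score as a covariate, with Ndufb3 at 1.35 ± 0.18. Cell cycle genes gave 11 higher and 1 lower (median 0.66, camera adjusted p = 0.0507), and 0 higher and 6 lower by library totals, and passed camera with the acinar score (adjusted p = 0.0418). Mki67 was at 1.04 ± 0.25 and Ccnd2 at −0.57 ± 0.17, but at −0.02 and 0.08 with the macrophage score as a covariate. Hmgcs1 was at 0.80 ± 0.16, and at −0.21 by library totals (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00809 or below for Hmgcs1, Mki67, Ccnd2, Ndufb3, Etv1, Aldh1a3, Hk1, Ldha and Slit1). By library totals Mki67 (0.01, edgeR adjusted p = 0.988), Etv1 (0.36, 0.29) and Ndufb3 (0.32, 0.383) did not pass. Nor did Mki67 with the acinar (1.46, edgeR adjusted p = 0.0648) or fibroblast score (0.41, 0.241), Ccnd2 with the fibroblast score (−0.25, 0.336), or Hmgcs1 (0.11, 0.766) and Ndufb3 (0.89, 0.0607) with the macrophage score. The markers of acinar cells (25 of 26, median 3.86, with the chymotrypsinogen Ctrb1 at 5.77 ± 0.78), fibroblasts (all 18, 2.71) and macrophages (all 17, 3.61) were higher in the same libraries. Their camera adjusted p was 2.24e-08, 3.79e-07 and 2.24e-08, and 0.378, 0.352 and 0.352 with an estimated correlation. Adjusted over the list alone the counts were the same, apart from 27 higher for the respiratory chain and 9 higher and 1 lower for the cell cycle among the lists given for this comparison.

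In higher-glucose Px 9043 of 15661 tested genes passed, 5045 higher (55.8%) and 3998 lower, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Library totals alone gave 1865 higher and 9074 lower (17% higher, median of all genes −0.96), and endocrine scaling 5153 higher and 2275 lower (69.4%, median 0.19). On simulated counts, 54% of genes changed 2-fold and 88% of those changed 4-fold were recovered in this comparison (15144 genes).

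**Figure D3:**
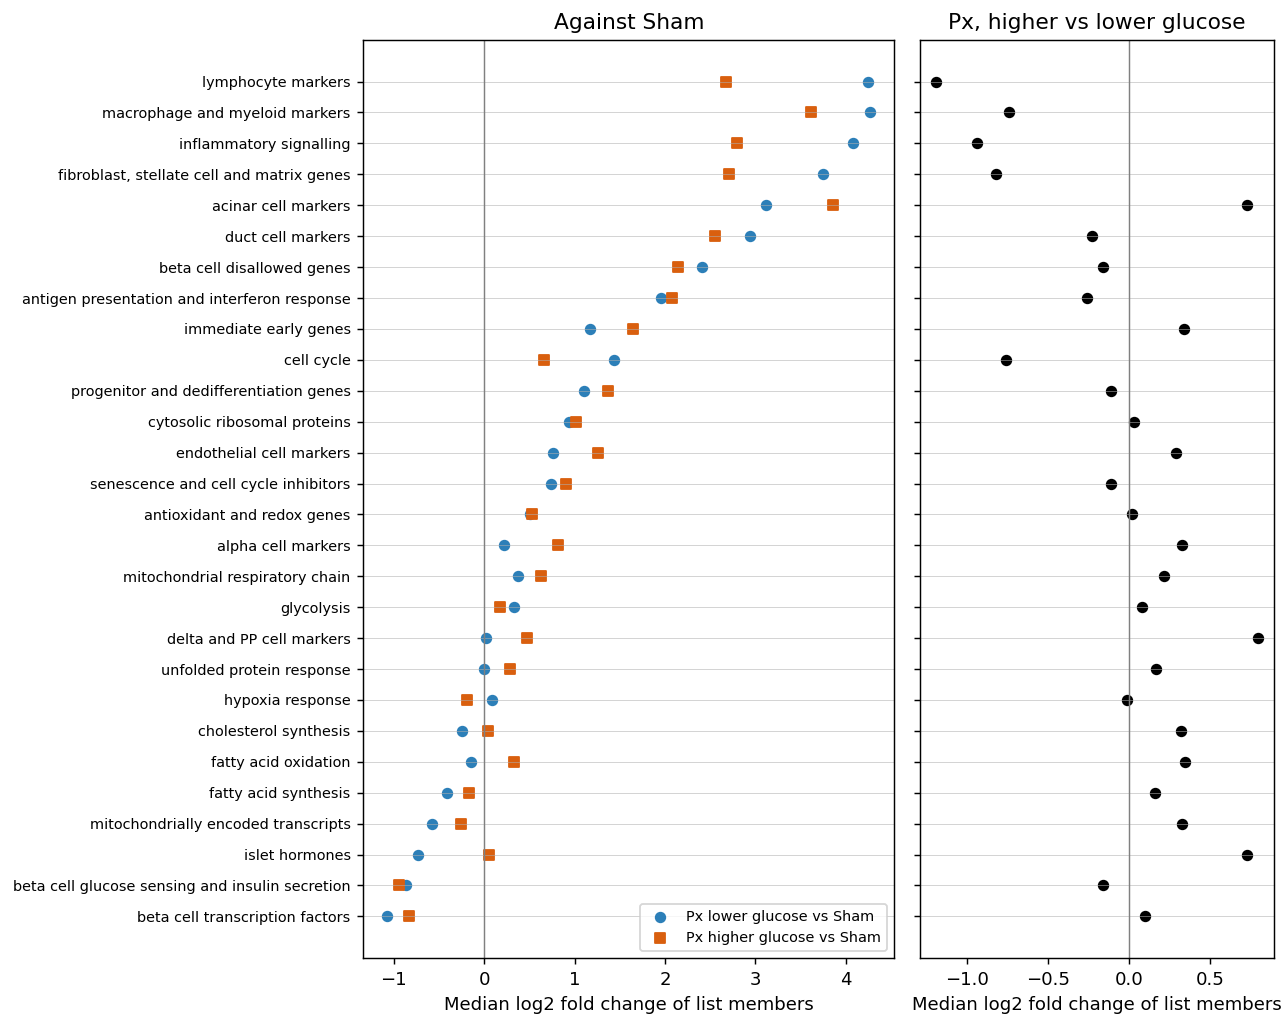
Median log2 fold change (horizontal axes) of the measured members of each of the 28 gene lists, in lower-glucose (circles) and higher-glucose (squares) Px against Sham (left panel) and in higher- against lower-glucose Px (right panel). Beta cell transcription factors and secretion genes lie left of 0 and acinar, fibroblast, macrophage and disallowed lists right of 0 against Sham under TMM, library totals and endocrine scaling alike, whereas lists with medians near 0, such as the respiratory chain, change sign by library totals.

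The direct comparison of higher- with lower-glucose Px asks which genes went with high blood glucose among rats that all had the same surgery. Somatostatin was higher: Sst was 241 ± 88 CPM in the 7 lower-glucose and 890 ± 106 CPM in the 3 higher-glucose libraries (1.88 ± 0.25, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000436). Cartpt (chromosome 2, 30125249 to 30127269), the precursor of the islet peptide CART, rose from 46.9 ± 18.3 to 270 ± 81 CPM (2.53 ± 0.30, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000191). Of 18 fibroblast and matrix genes 7 were lower, among them Col1a1 (chromosome 10, 82745801 to 82762789), the type I collagen chain, which fell from 1340 ± 599 to 296 ± 195 CPM (−2.17 ± 0.54, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0293). With the fibroblast score as a covariate none of the 3 passed (Sst 1.39, edgeR adjusted p = 0.1, Cartpt 2.08, 0.0588, and Col1a1 −0.74, 0.699), nor did Col1a1 with the macrophage score (−1.72, 0.144). Col1a1 is itself part of the fibroblast score, so its loss with that score follows in part by construction. Beta cell transcription factors and disallowed genes did not differ detectably between the 2 kinds of Px rats.

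**Figure D4:**
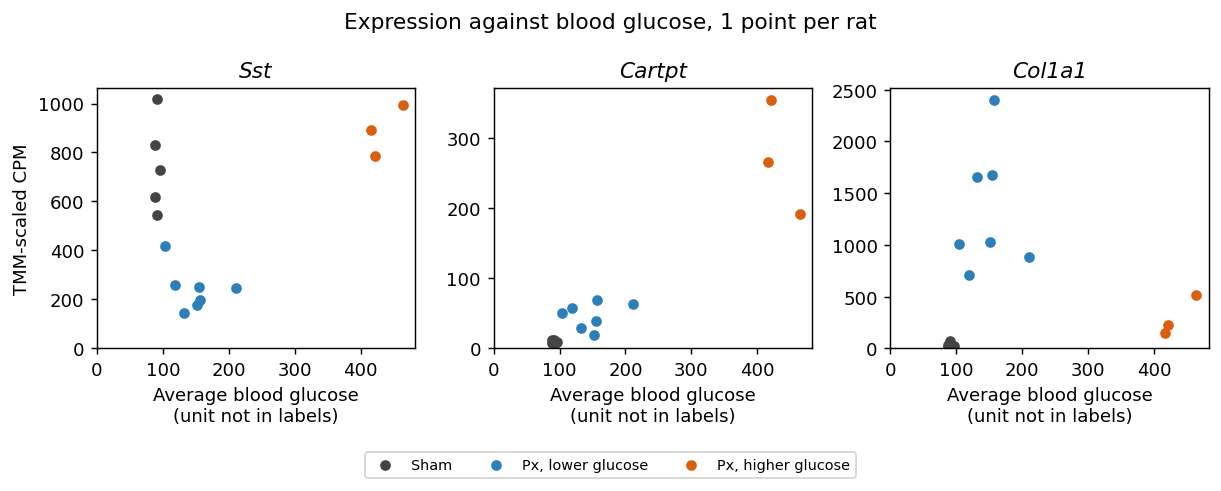
TMM-scaled CPM (vertical axes) of Sst, Cartpt and Col1a1 against average blood glucose (horizontal axes, unit not in the labels) in each library, 1 point per rat, coloured by group. Sst and Cartpt are higher and Col1a1 is lower in the 3 higher-glucose libraries than in each of the 7 lower-glucose libraries.

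Other large rises with high glucose, with all 3 higher-glucose libraries above the lower-glucose mean, were in Ppcdc, an enzyme of coenzyme A synthesis (3.47 ± 0.34), and Serpina6, the corticosteroid-binding globulin (2.64 ± 0.26). The group also held Nell2, a secreted neuronal glycoprotein (2.29 ± 0.22), Itgb8, an integrin that activates TGF-beta (2.24 ± 0.22), and Rgs16, a brake on G-protein signalling (2.03 ± 0.25, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.000213 or below for all 5). Rgs16 lost its call with the fibroblast score (1.61, edgeR adjusted p = 0.0636). The hormones gave 2 higher and 0 lower, and 4 higher adjusted over the list alone (median 0.73, camera adjusted p = 0.00944, and 0.281 with an estimated correlation), against 1 higher and 1 lower with endocrine scaling. Pyy rose by 0.94 ± 0.20, but not without higher-glucose replicate 15 (0.80, edgeR adjusted p = 0.0881). Delta and PP markers gave 3 higher and 1 lower, and 4 and 1 adjusted over the list alone (median 0.80, camera adjusted p = 0.0221, and 0.281 with an estimated correlation, 1 higher and 1 lower by library totals and 2 higher and 2 lower with endocrine scaling). Etv1 was at 0.94 ± 0.17. Among 31 secretion genes 2 higher and 2 lower passed, and 5 and 6 adjusted over the list alone (median −0.16, camera adjusted p = 0.548, 2 higher and 20 lower with endocrine scaling): Chgb (0.91 ± 0.13) and Cltrn, collectrin, which promotes exocytosis (0.86 ± 0.11), rose (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0128 or below for these and for Pyy and Etv1). By library totals none of the 4 passed (Chgb 0.43, edgeR adjusted p = 0.188, Cltrn 0.40, 0.158, Pyy 0.43, 0.239, and Etv1 0.40, 0.268). With the fibroblast score Cltrn (0.68, edgeR adjusted p = 0.0859), Pyy (1.11, 0.186) and Etv1 (0.88, 0.268) did not pass, nor Pyy with endocrine scaling (0.52, 0.0838) or the macrophage score (0.89, 0.0924). Glp1r fell from 82.3 ± 12.6 to 56.2 ± 1.61 CPM (−0.55 ± 0.13, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0198), but not without higher-glucose replicate 13 (−0.52, edgeR adjusted p = 0.122), 15 (−0.55, 0.0751) or 19 (−0.56, 0.0665) or with the fibroblast score (−0.66, 0.175).

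Beta cell transcription factors gave 0 higher and 0 lower (median 0.10, camera adjusted p = 0.4), although 3 were lower with endocrine scaling. Disallowed genes gave 0 higher and 0 lower (median −0.16, camera adjusted p = 0.394, 8 lower with endocrine scaling), and 0 of both lists passed adjusted over the list alone. Of the panel, Ins1 (−0.38 ± 0.39), Ins2 (−0.82 ± 0.37), Gcg (0.73 ± 0.29), Ppy (0.74 ± 0.26), Pdx1 (0.14 ± 0.14), Mafa (0.47 ± 0.34), Nkx6-1 (−0.12 ± 0.14), Ucn3 (−0.50 ± 0.17), Slc2a2 (−0.47 ± 0.16), Txnip (0.45 ± 0.40), Ldha (−0.66 ± 0.36), Hk1 (−0.10 ± 0.16) and Aldh1a3 (0.84 ± 0.25) did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 0.0674 to 0.735). Some passed with 1 library left out by the same edgeR test: Gcg without lower-glucose replicate 11 (0.92, adjusted p = 0.0469), Ucn3 without lower-glucose replicate 8 (−0.57, 0.0312), Slc2a2 without lower-glucose replicate 8 (−0.53, 0.0468), and Aldh1a3 without lower-glucose replicate 4 (0.95, 0.0489) or Sham replicate 24 (0.84, 0.0415). With endocrine scaling Ins2 (−1.27, edgeR adjusted p = 0.0217), Nkx6-1 (−0.52, 0.0296), Ucn3 (−0.92, 0.00105) and Slc2a2 (−0.90, 0.00525) were lower. Aldh1a3 was higher with the acinar share (0.93, edgeR adjusted p = 0.0462) and the fibroblast score (1.57, 0.029) and in DESeq2 and limma voom, and DESeq2 also passed Ins2, Ucn3 and Slc2a2.

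The fibroblast and matrix list gave 0 higher and 7 lower, and 13 lower adjusted over the list alone (median −0.82, camera adjusted p = 2.05e-06, and 0.427 with an estimated correlation). Adam12, a metalloprotease of activated stroma, fell by 2.48 ± 0.50 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00916), but not without higher-glucose replicate 13 (−2.13, edgeR adjusted p = 0.0637) or 19 (−2.39, 0.0522). Col1a1 did not pass without lower-glucose replicate 2 (−2.11, edgeR adjusted p = 0.0513) or higher-glucose replicate 13 (−1.84, 0.154) or 19 (−2.01, 0.117). Adam12 was −1.11 with the fibroblast score (edgeR adjusted p = 0.417). The cell cycle list gave 0 higher and 8 lower, and 1 higher and 19 lower adjusted over the list alone (median −0.76, camera adjusted p = 4.37e-09, and 0.327 with an estimated correlation, 0 higher and 0 lower by library totals). Top2a, a topoisomerase of dividing cells (−0.95 ± 0.22), and Cenpf, a centromere protein (−1.14 ± 0.26), fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0214 or below). Top2a lost its call without higher-glucose replicate 13 (−0.85, edgeR adjusted p = 0.125) or 19 (−0.93, 0.0813), and Cenpf without 13 (−0.98, 0.132), 15 (−1.21, 0.0639) or 19 (−1.22, 0.0595). Neither passed with the fibroblast (−0.30 and −0.41, edgeR adjusted p = 0.791 and 0.761) or macrophage score (−0.59 and −0.72, 0.161 and 0.165) or by library totals (−1.51 and −1.69, 0.0519 and 0.0564). The mean log2 level of the fibroblast list separated the groups in the same direction (6.89 ± 0.35, SD, n = 3, against 7.85 ± 0.39, SD, n = 7, exact two-sided permutation test, p = 0.00833).

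Several lists of metabolic genes moved up with glucose under TMM, though not by library totals or with endocrine scaling. Cholesterol synthesis gave 5 higher and 0 lower, and 10 higher adjusted over the list alone (median 0.32, camera adjusted p = 1.02e-05, and 0.327 with an estimated correlation), but 0 higher and 0 lower by library totals and 0 higher and 3 lower with endocrine scaling. Idi1, an isomerase of the pathway, rose by 0.77 ± 0.13. Fatty acid oxidation gave 3 higher and 0 lower, and 7 higher adjusted over the list alone (median 0.35, camera adjusted p = 0.000356, and 0.281 with an estimated correlation), but 0 higher and 0 lower by library totals and 0 higher and 2 lower with endocrine scaling. Its thiolase subunit Hadhb (0.36 ± 0.09) was −0.13 by library totals and −0.06 with endocrine scaling. It lost its call without lower-glucose replicate 2 (0.37, edgeR adjusted p = 0.0535) or 4 (0.36, 0.0573) and without higher-glucose replicate 13 (0.40, 0.0926), 15 (0.35, 0.115) or 19 (0.35, 0.105). Respiratory chain genes gave 3 higher and 0 lower (median 0.22, camera adjusted p = 1.02e-05, and 0.574 with an estimated correlation, 0 higher and 1 lower with endocrine scaling). Cox7b, a complex IV subunit, was at 0.83 ± 0.19, though not without higher-glucose replicate 19 (0.68, edgeR adjusted p = 0.104). Acaca, which starts fatty acid synthesis, rose by 0.74 ± 0.10 and Pfkfb3 by 1.54 ± 0.24 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0315 or below for these and for Idi1, Hadhb and Cox7b). By library totals Acaca (0.26, edgeR adjusted p = 0.33), Pfkfb3 (1.03, 0.0774), Idi1 (0.30, 0.386) and Cox7b (0.43, 0.132) did not pass, and with endocrine scaling Acaca (0.32, 0.071), Idi1 (0.32, 0.22) and Cox7b (0.40, 0.128) did not. With the fibroblast score none of the 5 passed (edgeR adjusted p from 0.1 to 0.567), nor did Hadhb (0.36, 0.136) and Cox7b (0.71, 0.123) with the macrophage score. Acinar (0.73, camera adjusted p = 0.00847), mitochondrially encoded (0.33, 0.000221), endothelial (0.29, 0.0221), unfolded protein response (0.17, 0.0309) and immediate early genes (0.34, 0.0233) had higher and inflammatory genes (−0.94, 0.00944) lower medians. With the acinar score the unfolded protein response did not pass camera (adjusted p = 0.0648). With an estimated correlation their camera adjusted p was 0.761, 0.427, 0.631, 0.761, 0.662 and 0.583. All but the acinar and inflammatory medians changed sign by library totals, and 1 gene of these 6 lists passed over all genes, against 4 mitochondrially encoded and 5 immediate early genes adjusted over the list alone.

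Of 15661 tested genes 764 passed in the direct comparison, 515 higher (67.4%) and 249 lower, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with n = 3 against n = 7. DESeq2 gave 1363 genes, 685 higher (50.3%) and 678 lower. Library totals alone gave 46 higher and 96 lower (32.4%, median of all genes −0.53), and endocrine scaling 171 higher and 4510 lower (3.65%, median −0.45), so the balance of rises and falls depended on the scaling. The granule genes used for endocrine scaling were themselves higher in these 3 rats (mean log2 CPM 10.27 ± 0.14, SD, n = 3, against 9.85 ± 0.19, n = 7, exact two-sided permutation test, p = 0.00833). Leaving out higher-glucose replicate 13 gave 270 genes, 15 378, 19 384 and lower-glucose replicate 2 468. On simulated counts, 52% of genes changed 2-fold and 90% of those changed 4-fold were recovered in this comparison (15120 genes).

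Within the 7 lower-glucose Px rats, whose glucose ran from 104 to 211, 0 of 13752 genes followed log2 glucose in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where 1277 had an unadjusted p under 0.05. Ints6l, a relative of an Integrator complex subunit (2.08 ± 0.23 per doubling, edgeR adjusted p = 0.216), Stab1, a scavenger receptor of macrophages and endothelium (−1.43 ± 0.18, 0.239), and Jag2, a Notch ligand (−1.12 ± 0.15, 0.239), came nearest. DESeq2 gave 121 genes (91 rising and 30 falling), edgeR without the filter on low counts 1, and limma voom 0. On simulated counts, 2% of genes changed 2-fold and 56% of those changed 4-fold per doubling were recovered (13820 genes), so smaller slopes were not detectable with these 7 libraries.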

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

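In this part the tests of dilution by other cells, of fewer beta cells, of acinar RNA and of immune-cell RNA were chosen only after the results were seen, as were the fibroblast, macrophage and acinar share covariates and the thinning as settings.

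Among 51 measures, 102 groups of 5 or 7 libraries were searched for a sample far from the others, and 9 met the criterion, where chance flags about 1 in 20 groups (5.1 here). The value given is the gap to the nearest library as a share of the group's range. Sham replicate 25 had the highest acinar share of its group (16.1% against 1.15% to 4.86%, gap 0.752). Sham replicate 23 had the lowest mean of the antioxidant list (4.487 against 4.808 to 4.939 log2 CPM, 0.711), and Sham replicate 27 the highest Slc2a2 (2095 against 1699 to 1772 CPM, 0.799). Lower-glucose replicate 11 had the lowest Ins1 (21850 against 42330 to 54130 CPM, 0.729), the lowest Ins2 (5893 against 11230 to 16860 CPM, 0.613) and the lowest progenitor list mean (3.313 against 3.644 to 3.86 log2 CPM, 0.605). Lower-glucose replicate 8 had the highest lymphocyte list mean (4.062 against 1.539 to 2.393 log2 CPM, 0.662), the highest hypoxia list mean (0.635) and the lowest Ucn3 (59.81 CPM, 0.585).

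The effect of Px against Sham differed between higher- and lower-glucose rats for panel genes in the direct edgeR test, among them Sst by 1.88 and Glp1r by −0.55 on the log2 scale.

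The beta cell transcription factors were lower in Px. Thinning every library to the smallest total left all 12 lower, which argues against the depth difference. Dilution of endocrine RNA by other cells would give an equal fall of genes made by endocrine cells alone. The list fell by 0.57 (−0.57) more than 8 granule genes shared by endocrine cells (Px −5.12 ± 0.26, n = 10, Sham −4.55 ± 0.17, n = 5, log2, exact two-sided permutation test, p = 0.000333, −1.38 to −0.13 with single granule genes). This range shows that the granule genes did not move equally either. Whether other cells also make them was not tested, so the larger fall does not by itself decide on dilution. Fewer beta cells among the endocrine cells stays open, since the list did not move relative to Ins1 and Ins2 (−0.03, exact p = 0.904), and for these 2 insulin genes dilution stays open as well (−0.54 relative to the granule genes, exact p = 0.141). Lower expression per beta cell after the surgery is a further hypothesis, not told apart from these by bulk RNA.

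The beta cell disallowed genes were higher in Px. RNA of acinar cells is argued against by 21 of 23 members still being higher with the acinar share as a covariate. RNA of immune cells could be a source: across the 10 Px libraries the list mean followed the macrophage score (r = 0.963, permutation p = 0.00024, adjusted p = 0.00192, rho = 0.867, permutation p = 0.00217, adjusted p = 0.00868, 4 relations, 8 tests), with r = 0.744 without lower-glucose replicates 8 and 14 and 0.969 within the 7 lower-glucose libraries. The lists share no gene, and C1qb, a macrophage marker, was 2.24 ± 0.788 CPM in Sham and 25.8 ± 5.71 CPM in Px. With the macrophage score as a covariate 16 members stayed higher (median 1.60 in place of 2.44), so a loss of repression in beta cells also stays open as a hypothesis. RNA of stromal cells stays open too. The fibroblast score was 4.32 ± 0.44 in Sham, 7.85 ± 0.39 in lower-glucose and 6.89 ± 0.35 in higher-glucose Px (mean ± SD). Its relation to the disallowed list across the Px libraries was not tested.

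Genes differed between higher- and lower-glucose Px. More acinar RNA with high glucose is argued against for the rising genes, since 80% of the 515 were still higher with the acinar share as a covariate. With the fibroblast score as a covariate, 5.24% of the 515 rising genes (27, median 0.76 before and 0.62 after) and 0.826% of the 242 falling genes outside the fibroblast list (2, −0.88 and −0.52) still passed, and all kept their sign. The predictions written before these tests took such a loss as a mark of stromal content, but the score itself separates the groups (exact p = 0.00833), which ends calls by construction, so fewer stromal cells cannot be told apart from an effect of glucose. Either could account for the pattern.

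Other splits of the libraries into groups of the same sizes show how often a random grouping gives as many genes, counting the real split. Of 3003, 792 and 120 possible splits a random 100 were used, the real one among them, and all 56 for higher-glucose Px against Sham. Chance was thus unlikely for each group comparison, but a share below 1 of 100 or 1 of 56 could not be shown. For Px against Sham 1 of 100 splits gave as many genes (9838, highest other 3921), for lower-glucose Px against Sham 1 of 100 (9949, 5890), for higher-glucose Px against Sham 1 of 56 (9043, 3593), and for higher- against lower-glucose Px 1 of 100 (764, 300).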

How the results depend on the processing

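Library totals alone, endocrine gene factors, the acinar share, macrophage and fibroblast covariates, the thinning and the 3 high-acinar libraries left out were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the groups share no replicate numbers.

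Counts of genes held within 1.5 times in most settings, and the exceptions follow; the cause was not tested unless given. A minimum absolute log2 fold change of 1 passes fewer genes by construction: 4029 for Px against Sham, 4225 for lower-glucose and 4335 for higher-glucose Px against Sham, and 279 for higher against lower glucose. The acinar score as a covariate gave 4149, 4787 and 3211 against Sham, and the macrophage score 3014, 701 and 2804, and 240 for higher against lower glucose. These scores differ between Px and Sham, so as covariates they take up part of the group difference. The fibroblast score gave 2584 for lower-glucose Px against Sham and 30 for higher against lower glucose, and the acinar share 5734 for higher-glucose Px against Sham. Higher against lower glucose moved most: DESeq2 gave 1363, the 2-group fit 506, weighted voom 1882, library totals 142 and endocrine factors 4681. Without high-acinar Sham replicate 25 and lower-glucose 14 and 16 it gave 1577. The slope within lower-glucose Px gave 0 genes, but 1 without a filter and 121 with DESeq2.

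Leaving out each library in turn gave 9297 to 9827 genes for Px against Sham, 9316 to 10057 for lower-glucose and 7932 to 9165 for higher-glucose Px against Sham, and 0 for the slope. For higher against lower glucose it gave 270 to 983: 270 without higher-glucose replicate 13, 378 without 15, 384 without 19 and 468 without lower-glucose replicate 2.

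With an estimated correlation 0 lists passed camera in each of the 4 comparisons, against 18, 19, 17 and 13 with the preset one. With the acinar score as a covariate 16, 16, 17 and 12 passed. Then acinar, antioxidant and respiratory chain lists no longer passed in the 3 comparisons with Sham, nor endothelial markers for all Px and lower-glucose Px (camera adjusted p = 0.0608 and 0.0741), nor the unfolded protein response for higher against lower glucose (0.0648). For the acinar list this follows largely by construction, since the score is the mean of its own genes. Passing with it alone were the unfolded protein response, downward for all Px and lower-glucose Px (camera adjusted p = 0.0158 and 0.0119), fatty acid synthesis, downward for all Px and higher-glucose Px (0.0315 and 0.0418), and for higher-glucose Px the cell cycle, upward (0.0418), and mitochondrially encoded transcripts, downward (0.0483). The cause of the other changes was not tested. Fry, which compares no list with other genes, gave 7 for higher against lower glucose.

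Of all genes the rule could name, 17 of 3653 gene and setting pairs changed sign for Px against Sham, 21 of 3686 for lower-glucose and 8 of 3283 for higher-glucose Px against Sham, and 2 of 2727 for higher against lower glucose. Among genes named in the text, these changed sign, and the cause was not tested. For Px against Sham the acinar score gave Ins2 0.16, the macrophage score Ece1 0.07, Ndufs1 0.09, Mki67 −0.13 and Ccnd2 0.13, the fibroblast score Sst 1.22 and Nr4a1 0.16, library totals Gcg −0.59 and Hmgcs1 −0.13, and endocrine factors Ndufs1 0.07. For lower-glucose Px against Sham the acinar score gave Ins2 0.17, the macrophage score Iapp 0.70, Scd −1.22, Hmgcs1 −0.60, Scg5 0.22 and Nell2 0.38, library totals Hmgcs1 −0.10, and the fibroblast score Hmgcs1 −0.15. For higher-glucose Px against Sham library totals gave Sst −0.75 and Hmgcs1 −0.21, and the macrophage score Mki67 −0.02 and Ccnd2 0.08. For higher against lower glucose Hadhb was −0.13 by library totals and −0.06 with endocrine factors.

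Calls that ended without a change of sign were most frequent with covariates. Named genes numbered 60 for Px against Sham, 28 and 25 for lower- and higher-glucose Px against Sham, and 45 for higher against lower glucose. Some had no call to lose. In that order the macrophage score ended 16, 18, 7 and 11 and the acinar score 13, 5, 5 and 0. The fibroblast score ended 5, 12, 3 and 25. Losses of genes on a score's own list follow in part by construction. Library totals ended 3, 0, 6 and 17, and endocrine factors 4, 6, 0 and 5. The cause was not tested.

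Changes of 1.5-fold were recovered on simulated counts for 26% of genes in higher against lower glucose and for 36% in Px against Sham. These counts had the real library sizes but no difference in cell content between groups. Thinning every library to the smallest total gave 588 and 9128 genes.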

Other observations

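The genes in this part were chosen after their values were seen, and the list of carbohydrate-responsive genes was written before its test.

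Scg3, Scg5, Rbp4 and Nell2 were lower in lower-glucose Px than in Sham and higher in higher- than in lower-glucose Px, as Sst was. Chgb was not lower in lower-glucose Px (0.09 ± 0.12, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.508). Scg3, a granin of secretory granules, was 927 ± 142 CPM in Sham, 596 ± 105 in lower-glucose and 1030 ± 117 in higher-glucose Px (−0.64 ± 0.14 for lower glucose against Sham, 0.79 ± 0.16 for higher against lower glucose). Scg5, a chaperone of hormone processing, gave −0.62 ± 0.14 and 0.91 ± 0.16, Rbp4 −0.69 ± 0.15 and 0.87 ± 0.17, and Nell2 −1.19 ± 0.19 and 2.29 ± 0.22 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0089 or below for all 8 values). Library totals ended the second calls of Scg3 (0.34), Scg5 (0.45) and Rbp4 (0.40), and endocrine scaling both calls of Rbp4 (−0.12 and 0.46). That scaling is built from Scg3, Scg5 and Chgb among others, so it does not test these genes. With the macrophage score as a covariate the first values were −0.08, 0.22, −0.11 and, for Nell2, 0.38, and none passed, nor did the second values of Scg3 (0.65), Scg5 (0.70) and Rbp4 (0.72). With the fibroblast score none of the first calls held, and of the second only that of Nell2. Scg3 lost its second call without higher-glucose replicate 19 (0.70, edgeR adjusted p = 0.0594), and Rbp4 without 15 (0.77, 0.0522). Hhex, a transcription factor of delta cells, did not differ detectably between higher- and lower-glucose Px (0.15 ± 0.17, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.621).

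Tph1, which makes serotonin, was 0.6 ± 0.256 CPM in lower-glucose and 2.85 ± 0.887 CPM in higher-glucose Px (2.27 ± 0.43), and Pkib, a protein kinase A inhibitor, 4.08 ± 1.05 and 10.7 ± 1.61 CPM (1.40 ± 0.20, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00608 or below). Tph1 lost its call by library totals (1.82, edgeR adjusted p = 0.0687) and with the macrophage (2.01, 0.0757) and fibroblast scores (2.0, 0.325), and Pkib by library totals (0.90, 0.0806) and with the fibroblast score (1.17, 0.166). Pkib (3.70 ± 0.44) and Lepr, the leptin receptor (2.11 ± 0.30), were higher in all Px than in Sham. Gad2, which makes GABA in beta cells (−1.92 ± 0.17), and Slit1 (−1.77 ± 0.25) were lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 1.33e-05 or below for all 4), and Pkib (2.45, edgeR adjusted p = 0.0772) and Slit1 (−1.49, 0.0621) lost their calls with the acinar score. Gad2 (−0.80 ± 0.14) and Slit1 (−1.23 ± 0.19) were lower still in higher- than in lower-glucose Px (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00415 or below), but not with the fibroblast score (−0.78 and −1.28, edgeR adjusted p = 0.156 and 0.0549).

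With high glucose Mid1ip1, a lipogenic regulator (1.11 ± 0.10), Gpd1, a glycerol phosphate dehydrogenase (1.45 ± 0.22), and Acacb, an acetyl-CoA carboxylase (1.5 ± 0.33), were higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0147 or below), Acacb not without higher-glucose replicate 13 (1.42, edgeR adjusted p = 0.0799) or 15 (1.15, 0.12). By library totals Mid1ip1 (0.62, edgeR adjusted p = 0.0778) and Acacb (1.01, 0.0769) did not pass, nor Gpd1 (0.89, 0.233) and Acacb (0.98, 0.587) with the fibroblast score, nor Acacb with the macrophage score (1.25, 0.138). The hypothesis was that this rise extends to other genes that carbohydrate induces (Pklr, Arrdc4, Khk, Tkfc, Pnpla3, Klf10, Agpat2 and Tkt). Camera gave p = 0.0659 for the 8 genes (0.0814 with an estimated correlation), above the 0.05 set beforehand, so the prediction was not met. The median log2 fold change was 0.18 with 7 of 8 above 0, and 1 gene, Klf10, passed (0.46 ± 0.11, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0221). The bound written beforehand would have counted this against the hypothesis, but a p above a threshold does not exclude a rise in 8 genes, so it stays open.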
